A study of Mus musculus with 2 samples.

How the data were processed

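Single-cell RNA was profiled in 2 tumors of epithelioid hemangioendothelioma from mice. Per the labels' protocols, the tumors were frozen slowly in medium with DMSO and serum, thawed, dissociated with an enzymatic tumor dissociation kit and made into 10x Genomics droplet libraries. The deposited files hold, per the labels, unique molecular identifier (UMI) counts per gene and barcode, as whole numbers without normalization. Per the submitters' processing notes, Cell Ranger 3.0.2 and the mouse build mm10 were used; how barcodes were separated from empty droplets is not given in the sources used here. Each tumor's matrix was deposited as 2 copies with identical values, and 1 copy was used. The matrices list 31053 genes, and 30934 of their gene IDs are in GENCODE M21 for GRCm38 (mm10), from which positions were taken, 1-based.

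Cells with at least 500 detected genes and at most 20% mitochondrial counts were kept. Scrublet, run per tumor, marked 2 and 22 cells (0.28% of 8613) as doublets. These were removed, but so low a share was not relied on. The labels do not say whether doublets had been removed before deposit. An added setting removed the top 5% of doublet scores instead (431 cells). Counts were scaled to 10000 per cell and log transformed. Both tumors were clustered together in scanpy 1.11.5 on 2000 variable genes, 30 principal components and 15 neighbors with Leiden clustering at resolution 0.5 and no batch correction. The 391 genes of 21 lists fixed before the data were examined were left out of the clustering features. A cluster took the name of the class whose fixed markers were seen in the highest mean share of its cells, if at least 3 of them were seen in at least 20% of cells. A cluster stayed unnamed if 3 times its median UMI count was below the median of a tumor and none of its 10 leading genes was a marker of the class, or if those genes held at least 2 markers of another class and more than of its own; the details of this naming rule were set after the data were seen. Intervals of shares are 95% Clopper-Pearson intervals and cover counting error only.

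Raw counts were summed per tumor and class for the 5 classes with at least 20 cells in each tumor. edgeR 4.0.16 (glmQLFit and glmQLFTest) fitted the 10 sums with class and tumor as terms, TMM scaling and filterByExpr, which left 11447 genes, 370 of them listed, and 4 residual degrees of freedom. The tumor entered as a block because all classes of a tumor come from the same tissue. Each contrast set a class against the mean of the log levels of the others, so its sign can differ from that of mean CPM values. The 5 endothelial-like clusters were fitted in the same way (10887 genes, 335 listed). p-values were adjusted by Benjamini-Hochberg over all genes tested and again over each list alone. Calls refer to 5% FDR. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and at an estimated correlation. At the preset value 92 of 210 tests were called. At the estimated correlation camera called 0 of 210, and 22 had an unadjusted p under 0.05. Its p also rose in some tests whose estimated correlation lay below the preset value. For targets and feedback genes of ERK signaling in fibroblast-like cells the estimate was −0.014. Camera's unadjusted p there was 6.2e-05 at the preset value and 0.013 at the estimate. The loss of calls can therefore not be put down to correlation alone. R was version 4.3.3. TMM was replaced by DESeq2 size factors as an alternative, which moved the median log2 fold change of all genes in the endothelial-like contrast by −0.11 and no other by more than 0.1.

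The genes named in the text follow a rule set in advance, apart from cell-type and vessel-type markers of fixed lists, leading genes of clusters, and genes given as chosen after their values were seen. In each list and contrast it took up to 3 genes with the largest change among those past 5% FDR and changed in the same direction in both tumors. In the endothelial-like contrast 10 genes were always included, of which Ankrd1 did not pass the filter on low counts. The rule gave 559 gene and contrast pairs. The text gives those with enough counts on both sides for a fitted fold, and no fold is given for genes with 0 counts in a group. Between tumors, listed genes with at least 50 counts and a fold of at least 4 after TMM scaling and the addition of 0.5 counts were eligible, so that folds differ slightly from ratios of the printed CPM values, and a list's median log2 ratio was set against 10000 random lists matched on level. Shares of cells with a UMI were compared after thinning every cell to 1500 UMIs, leaving out shallower cells.

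The procedure was tested on simulated counts with 200 changed genes. For the endothelial-like contrast (11447 genes) it recovered 65% of genes changed 2-fold and 96% of those changed 4-fold, and 10.6% of its calls were false. For E5 (10887 genes) it recovered 43% and 79%, and 5.4% of its calls were false. Camera at the preset correlation found the 1 changed list and none of 20 unchanged lists in each simulation. The simulated genes varied independently, whereas the estimated correlation in the data was 0.84 for the G2/M genes in E4. The simulation therefore does not show that camera's calls at the preset correlation hold for correlated lists. Its 200 changed genes rose and fell equally often. In the data, 169 of 370 listed genes were called higher and 82 lower in the endothelial-like contrast. The shares recovered and falsely called may therefore differ for the data. Alternatives tried were DESeq2 1.42.0 (Wald test), its size factors in edgeR, no filter on low counts, no tumor block, each tumor left out, each other class alone as reference, a cell filter of 200 genes and 10% mitochondrial counts, doublets kept, Leiden resolution 1.0, tumors clustered alone, listed genes as clustering features, and thinned cells. Added after seeing the data were the removal of the top 5% of doublet scores, cluster U1 counted as endothelial-like, cluster E5 left out, and thinned cells in the cluster comparison. For the endothelial-like contrast, tumors clustered alone and listed genes as features were also added then; for the shares they were set in advance.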

Results

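Gene expression was measured in individual cells of 2 epithelioid hemangioendothelioma (EHE) tumors from a genetically engineered mouse model. EHE is a sarcoma of vascular cells, and most human cases carry a fusion of WWTR1 (TAZ, a transcriptional coactivator of the Hippo pathway) with the transcription factor CAMTA1. Both tumors grew on the peritoneal surface of C57BL6 mice and form 1 group, with no control tissue, so the comparisons lie between cell classes within the tumors. Tumor 1 gave 5850 barcodes with 29023568 unique molecular identifiers (UMIs), and tumor 2 gave 4108 barcodes with 33226746 UMIs. After filtering, 4952 and 3637 cells remained, with medians of 3397 and 5898 UMIs per cell. The labels do not say whether the tumors came from separate animals. The tumor term takes up the common difference between the tumors. The p-values therefore measure only how far differences between classes or clusters varied between these 2 tumors.

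The first question was which cells made up the tumors. Endothelial-like cells formed the largest class, at 55.0% of kept cells in tumor 1 (95% Clopper-Pearson interval 53.6% to 56.4%) and 68.0% in tumor 2 (66.5% to 69.5%), a mean of 61.5% ± 9.22 (SD, n = 2). They were named from Pecam1, Cdh5, Tie1, Tek and further endothelial markers. B-cell-like cells made up 11% ± 4.0 (SD, n = 2), T-cell-like cells 9.06% ± 3.41 and macrophage-like cells 7.66% ± 1.73. Fibroblast-like cells made up 4.26% ± 0.544 and plasma-cell-like cells 0.265% ± 0.025. Tumor 1 held more B-cell-like and T-cell-like cells (13.8% and 11.5%) than tumor 2 (8.14% and 6.65%). Clusters without a name held 9.15% of the cells of tumor 1 and 3.41% of those of tumor 2. Nearly all of these belonged to cluster U1, led by the noncoding RNAs Gm26917, Kcnq1ot1, Lncpint and Neat1, with medians of 1198 and 1404 UMIs per cell. The unnamed share fell to 0.3% with a filter of 200 genes and 10% mitochondrial counts, where the endothelial-like share was 67.1%. The intervals cover counting error only.

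**Figure D1:**
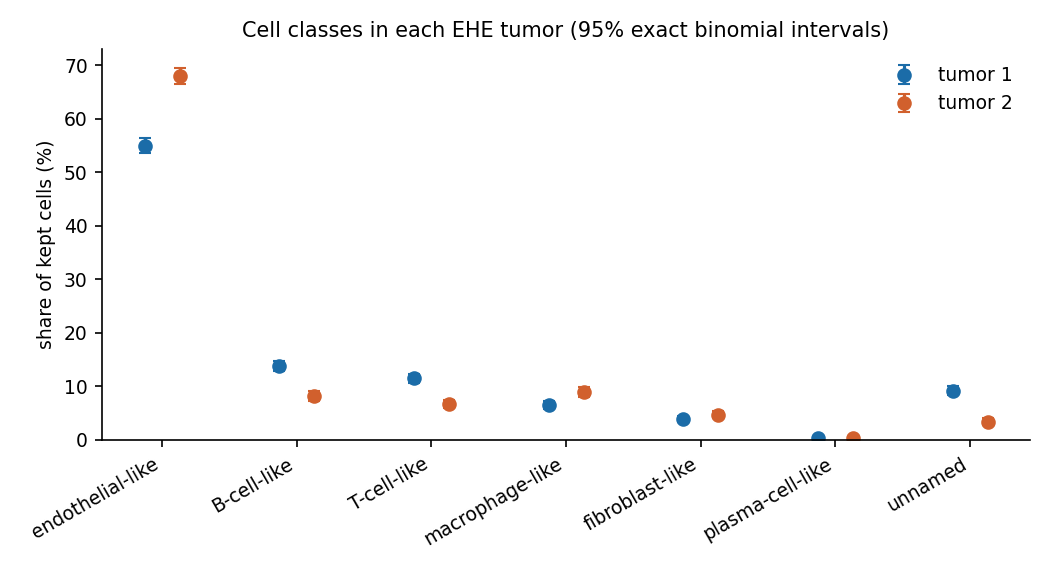
Share of kept cells (%) in each named cell class, 1 point per tumor, with 95% exact binomial intervals as bars. Endothelial-like cells made up 55.0% of tumor 1 and 68.0% of tumor 2.

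The main comparison asked which regulatory programs set the endothelial-like cells apart from the other 4 testable classes. Of the Hippo pathway list, 14 of 21 genes were higher in the endothelial-like cells. This list also held Camta1 and Camta2, and Camta1 was among the 14. Of the targets of the Hippo coactivators YAP and TAZ, 10 of 19 were higher. Wwtr1 was 2.75 ± 0.27 higher (log2 fold change ± SE, n = 2 tumors) and Camta1 2.20 ± 0.16. Yap1, the paralog of Wwtr1, was 2.49 ± 0.21 higher. Their DNA-binding partners Tead2 and Tead4 were higher by 3.07 ± 0.25 and 2.76 ± 0.25, and the TEAD cofactor Vgll3 by 3.51 ± 0.27. Among YAP/TAZ targets, the matricellular genes Cyr61 and Ctgf were higher by 3.21 ± 0.13 and 2.68 ± 0.22, and the junction gene Amotl2 by 3.22 ± 0.17. Cyr61 reached 2773 ± 1296 CPM (counts scaled to a common library size; SD, n = 2) in endothelial-like cells against 390 ± 192 averaged over the other classes. The largest adjusted p among these 9 genes was 4.7e-06 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment). Not every YAP/TAZ target followed. Nt5e, an ectonucleotidase, was at −5.23 ± 0.35 and the receptor kinase Axl at −3.53 ± 0.63, as their RNA lay mostly in T-cell-like cells (Nt5e) and in macrophage-like and fibroblast-like cells (Axl).

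In GRCm38, Wwtr1 (ENSMUSG00000027803) lies on chromosome 3 from 57455649 to 57575910, and Camta1 (ENSMUSG00000014592) on chromosome 4 from 150917322 to 151861876. Cyr61 (ENSMUSG00000028195) lies on chromosome 3 from 145646976 to 145649981. The counts are per gene, so they do not separate reads of a fusion transcript from reads of the normal alleles.

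In the Hippo list 2 genes were lower and 5 not called, and among YAP/TAZ targets 2 were lower and 7 not called. Both lists ranked above other genes in the camera test (adjusted p = 0.011 and 0.043). Neither did with an estimated correlation (adjusted p = 0.39 and 0.69 with an estimated correlation). Angiogenic genes were higher for 14 of 19, including the VEGF receptor Kdr (3.45 ± 0.24) and the vessel-destabilizing ligand Angpt2 (3.39 ± 0.30). Of the TGF-beta and BMP list, 12 of 17 were higher, including the co-receptor Eng (3.08 ± 0.20), the ligand Bmp6 (3.49 ± 0.27) and the BMP target Id1 (3.04 ± 0.28). In the Notch list 7 of 9 were higher, including the ligand Jag2 (3.40 ± 0.44) and the target Hes1 (2.23 ± 0.23). Targets and feedback genes of ERK signaling were higher for 11 of 16, including the cyclin Ccnd1 (2.73 ± 0.18). Extracellular matrix genes were higher for 16 of 27 and lower for 5; the basement membrane chain Lamb1 stood at 3.01 ± 0.22 and osteopontin, Spp1, at −4.14 ± 0.66. Camera gave these 5 lists adjusted p of 0.0047, 0.028, 0.014, 0.028 and 0.028. The values were 0.39, 0.39, 0.39, 0.39 and 0.71 as adjusted p with an estimated correlation.

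**Figure D2:**
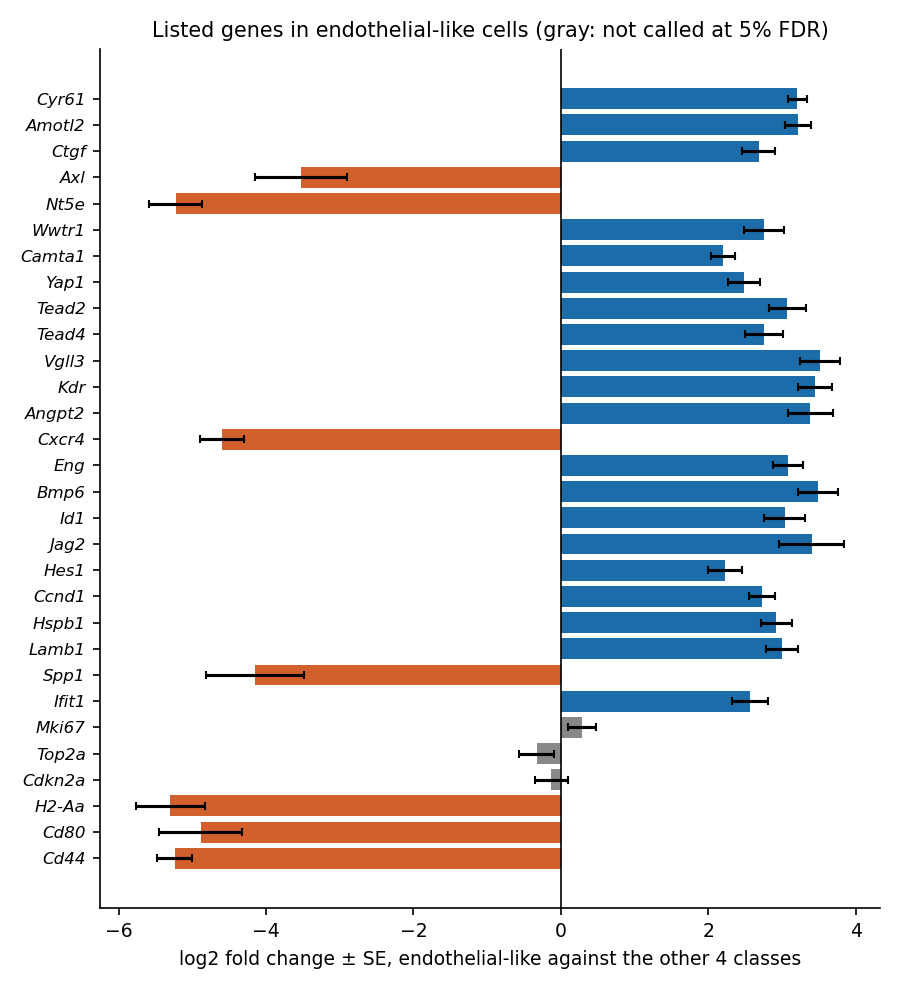
Log2 fold change ± SE (n = 2 tumors) of listed genes in endothelial-like cells against the mean of the other 4 classes, with genes higher in blue, lower in orange and not called in gray. Wwtr1 stood at 2.75 and Camta1 at 2.20, while Cdkn2a, at −0.13, was not called.

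Immune genes did not move as 1 block. All 9 MHC class II genes, which present antigen to helper T cells, were lower in endothelial-like cells, with H2-Aa at −5.30 ± 0.47. Of the immune checkpoint genes 13 of 21 were lower, such as the costimulatory ligand Cd80 (−4.89 ± 0.57). The adhesion receptor Cd44 (−5.24 ± 0.24) and the chemokine receptor Cxcr4 (−4.59 ± 0.30) were lower as well. Of the MHC class I genes 3 of 14 were lower and 11 were not called. Chemokines and cytokines split, with 10 of 33 higher and 14 lower. In the interferon list 7 of 12 were higher, with Ifit1 at 2.56 ± 0.24. The stress genes induced by tissue dissociation were higher for 14 of 20, with the heat shock gene Hspb1 at 2.92 ± 0.21, a response also known from the handling of tissue. Camera's adjusted p was 4.4e-07 for MHC class II genes, 0.028 for checkpoint genes and 0.015 for stress genes. They were 0.39, 0.39 and 0.71 as adjusted p with an estimated correlation. The proliferation genes Mki67 (0.29 ± 0.19, adjusted p = 0.25 in edgeR's quasi-likelihood test) and Top2a (−0.33 ± 0.24, adjusted p = 0.28) were not called. Neither was the cell cycle inhibitor locus Cdkn2a (−0.13 ± 0.23, adjusted p = 0.8).

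In all, 169 of 370 listed genes were higher in endothelial-like cells, 82 were lower and 119 were not called. Adjusted over the list alone, 171 were higher and 83 lower. Against fibroblast-like cells alone only 61 were higher, and against B-cell-like cells alone 52 were lower. Hspb1 turned to −0.17 against fibroblast-like cells alone, and Axl to 0.025 against B-cell-like cells alone.

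The endothelial-like cells fell into 5 clusters, numbered E1 to E5, with 1658, 1495, 948, 758 and 338 cells. E1 came mostly from tumor 2 (1393 cells) and E2 mostly from tumor 1 (1401 cells). E3 to E5 held at least 118 cells of each tumor. Among the fixed vessel-type markers, some split them into E1 to E4 on one side and E5 on the other; those named here were chosen after their values were seen. Prox1, the transcription factor that specifies lymphatic endothelium, stood at 670 and 551 CPM in E1 (tumors 1 and 2), 469 and 368 CPM in E2, 690 and 515 CPM in E3, and 644 and 611 CPM in E4. In E5 it stood at 108 and 70.5 CPM. In cells thinned to 1500 UMIs, 37.7% to 56.8% of cells in E1 to E4 had a Prox1 UMI, against 9.2% and 6.7% in E5. B-cell-like cells, which should lack Prox1, gave 6.9% and 4.4%, a background share that E5 did not exceed beyond its interval. Unthinned, the shares were 61.2% to 93.1% in E1 to E4, 12.7% and 8.64% in E5, and 9.52% and 5.07% in B-cell-like cells. Median depth was 2415 and 2042 UMIs in E5 and 2323 and 2892.5 UMIs in B-cell-like cells. Flt4, the receptor for lymphatic growth factors, parted them less, at 67.6 to 166 CPM in E1 to E4 and 34.1 and 69.0 CPM in E5. Pdpn, another lymphatic marker, stayed between 0.88 and 8.4 CPM in E1 to E4, so the clusters did not carry the whole lymphatic set. Gpihbp1, a capillary marker, stood at 756 and 1216 CPM in E5 and at no more than 2.19 CPM in any of E1 to E4. Prox1 (ENSMUSG00000010175) lies on chromosome 1 from 190118035 to 190170714.

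**Figure D3:**
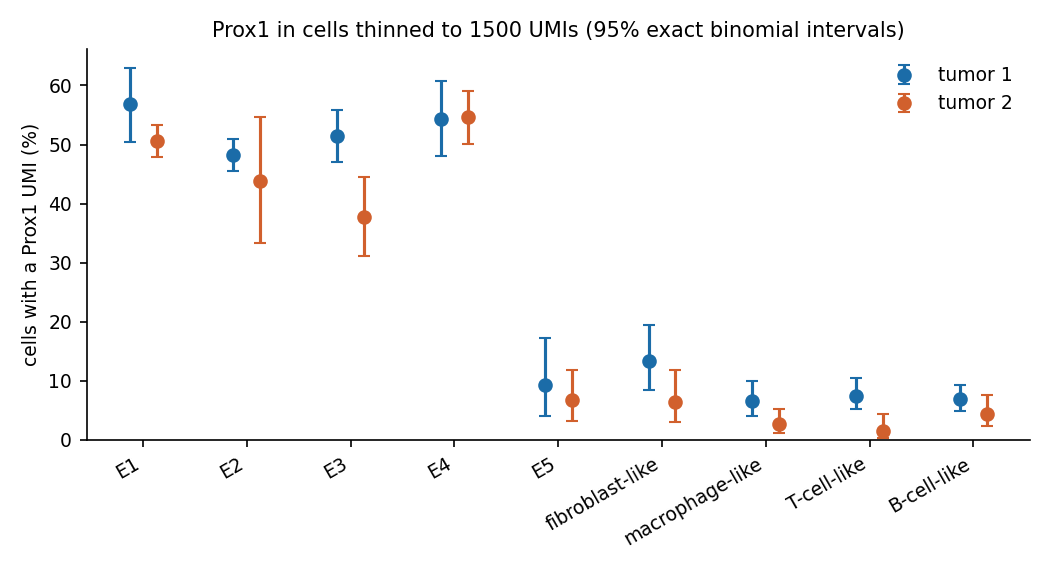
Share of cells (%) with at least 1 Prox1 UMI after thinning to 1500 UMIs, for each cluster or class, 1 point per tumor with 95% exact binomial intervals. E1 to E4 lie between 37.7% and 56.8%, E5 at 9.2% and 6.7% and B-cell-like cells at 6.9% and 4.4%.

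Cluster E5 was compared with the mean of E1 to E4 on listed genes that had no part in the clustering, though unlisted genes that vary with them did. The same limit holds for the comparisons of E1 to E4 below. Angiogenic genes were higher in E5 for 13 of 21 and lower for 4, and Notch genes went both ways, 6 of 10 higher and 3 lower. The VEGF co-receptor Nrp1 was higher by 8.94 ± 0.25 and the junction gene Jam2 by 8.72 ± 0.23. The chemokine Cxcl12, a CXCR4 ligand, was higher by 9.69 ± 0.18, at 970 ± 161 CPM against 1.22 ± 0.071. Notch4 was higher by 5.44 ± 0.36, the Notch target Hey1 by 3.07 ± 0.27, and Epas1, which encodes HIF-2 alpha, by 2.67 ± 0.11. The receptor Notch2, chosen after its value was seen, was lower, at −2.18 ± 0.30. Interferon genes were higher for 11 of 12, including the antiviral gene Rsad2 (5.41 ± 0.69). The checkpoint ligand Cd274, which encodes PD-L1, was higher by 2.53 ± 0.26. Hypoxia and glycolysis genes went the other way, with 13 of 20 lower, such as the oxygen sensor gene Egln3 (−3.02 ± 0.36) and Ankrd37 (−2.37 ± 0.30). In the Hippo list 7 of 20 were lower and 2 higher, with Vgll3 at −4.02 ± 0.42. Chosen after their values were seen, Wwtr1 stood at −0.85 ± 0.21 in E5 (adjusted p = 0.0063, edgeR's quasi-likelihood test) and Camta1 at −0.58 ± 0.16 (adjusted p = 0.015). Yap1, chosen likewise, stood at −0.01 ± 0.20 (adjusted p = 0.99). YAP/TAZ targets went both ways, with 6 of 15 higher and 5 lower. Igfbp3 and Axl were higher by 5.63 ± 0.24 and 2.64 ± 0.74, while Cyr61 and Ctgf, chosen after their values were seen, stood at −1.07 ± 0.15 and −1.10 ± 0.33.

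Across the lists, 107 of 335 genes were higher in E5 and 68 lower (111 and 78 adjusted over the list alone). Camera placed the angiogenic (adjusted p = 1.8e-08), interferon (2e-05), adhesion (2e-05) and Notch lists (0.0067) higher and the hypoxia list lower (0.00097). These were 0.41, 0.48, 0.27, 0.41 and 0.48 as adjusted p with an estimated correlation. MHC class II genes were higher for 4 of 7, but 2 of the 118 E5 cells of tumor 1 held 70.3% of their H2-Aa, H2-Ab1 and H2-Eb1 UMIs. Without those cells H2-Aa stood at 82.1 CPM, against 67.1 CPM in E1 to E4 of that tumor. Acta1, a skeletal muscle actin and 1 of the leading genes of E5, was at 1850 CPM in E5 of tumor 2 and at 21.7 CPM in E5 of tumor 1.

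Cluster E4 showed UMIs of Mki67 or Top2a most often among the endothelial-like clusters, but in a minority of its cells. At Leiden resolution 1.0, a cluster with Ube2c and Mki67 among its leading genes stood apart from one led by Aqp8 and Cldn11. The leading genes of E4 included Aqp8 and Cldn11 and no cell cycle gene. Such UMIs were seen in 1.0% to 1.64% of thinned cells of E1, E2, E3 and E5, against 8.22% in E4 (21.55% unthinned). All 24 genes of the G2/M list were higher than in the other endothelial-like clusters, with the ubiquitin ligase partner Ube2c at 5.34 ± 0.19 and cyclin Ccnb2 at 5.19 ± 0.65, as were 16 of 20 S-phase genes, with the ribonucleotide reductase chain Rrm2 at 2.95 ± 0.22. The interferon list was lower for all 12 genes tested, with Ifit3 at −3.11 ± 0.56, and MHC class I genes for 11 of 14, with the immunoproteasome genes Psmb8 and Psmb10 at −1.26 ± 0.15 and −1.28 ± 0.14. Cd274 stood at −2.25 ± 0.23. Fibronectin, Fn1, was higher by 1.43 ± 0.15 and the cytokine gene Csf2 by 2.75 ± 0.34. By camera the adjusted p was 2.7e-44 for G2/M, 2.4e-14 for S phase, 8.3e-08 for interferon and 1.8e-07 for MHC class I genes. They were 0.26, 0.13, 0.41 and 0.41 as adjusted p with an estimated correlation. The total was 96 of 335 higher and 87 lower (110 and 92 adjusted over the list alone), but 55 and 55 in thinned cells and 59 and 32 without the tumor block, and E4 had the deepest cells, with medians of 8958 and 13163 UMIs. Against E1 to E3 alone, chosen after seeing the data, 57 genes were lower and 9 of 11 interferon genes remained lower.

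Cluster E3 was the shallowest of E1 to E4, with medians of 2624 and 4019 UMIs, and its cells showed the endothelial markers least often (a mean of 38.3% of cells per marker, against 54.6% to 65.3% in the other clusters). Of the hypoxia and glycolysis list, 12 of 20 were higher, including Egln3 (2.08 ± 0.18) and Ankrd37 (1.20 ± 0.18). The vasodilator Adm (1.95 ± 0.14) and Angpt2 (1.56 ± 0.12) were higher too. Stress genes were lower for 17 of 20, with the immediate early gene Nr4a1 at −1.51 ± 0.16. ERK feedback genes were lower for 9 of 15, with Fosl1 at −2.91 ± 0.26, and chemokines for 9 of 21, with the monocyte attractant Ccl2 at −2.56 ± 0.26. In camera the adjusted p was 5e-11, 9.2e-21, 6.1e-12 and 5.8e-12 for these 4 lists, and 0.13, 0.13, 0.1 and 0.11 as adjusted p with an estimated correlation. In all 28 of 335 genes were higher and 86 lower (35 and 105 adjusted over the list alone). Without the tumor block 11 were higher and 38 lower, in thinned cells 54 were lower, and without E5 in the fit 16 were higher.

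Cluster E2, mostly from tumor 1, carried inflammatory genes. Chemokines and cytokines were higher for 12 of 21, with Ccl2 at 2.65 ± 0.19 and 3812 ± 444 CPM (SD, n = 2). The leukocyte adhesion molecule Vcam1 was higher by 2.38 ± 0.33. Interferon genes were higher for 8 of 12, with the guanylate-binding protein Gbp2 at 2.05 ± 0.31, MHC class I genes for 7 of 14, with the heavy chain H2-K1 at 0.68 ± 0.13, and stress genes for 15 of 20, with Atf3 at 0.92 ± 0.15. Wwtr1 (0.85 ± 0.13), Camta1 (0.75 ± 0.12) and Cyr61 (0.88 ± 0.13) were also higher in E2, and the VEGF receptor Flt1 was at −1.91 ± 0.19. Camera's adjusted p was 2e-15 for chemokines, 1.7e-08 for interferon, 5.7e-05 for MHC class I and 1.2e-10 for stress genes. They were 0.063, 0.18, 0.25 and 0.25 as adjusted p with an estimated correlation. Without E5 in the fit, chosen after seeing the data, camera called the chemokine list at adjusted p = 0.028 with an estimated correlation. It was not called with E5 included. The fit without E5 left 3 residual degrees of freedom. The correlation estimated for this list was −0.026 without E5, below the preset 0.01, and 0.05 with E5. In all 87 of 335 genes were higher and 20 lower (103 and 25 adjusted over the list alone), but 24 and 7 without the tumor block.

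Cluster E1, mostly from tumor 2, differed least, with 31 genes higher and 15 lower (48 and 32 adjusted over the list alone). Matrix genes were higher for 7 of 23, with the collagen chain Col5a1 at 1.64 ± 0.26 and the membrane protease Mmp14 at 1.34 ± 0.16. The angiogenic factors Adm and Pgf were higher by 1.43 ± 0.14 and 1.18 ± 0.27. Hypoxia and glycolysis genes were higher for 4 of 20 and lower for 1 (13 and 1 adjusted over the list alone), with the glycolysis gene Pgk1 at 0.73 ± 0.17 and Epas1 at −0.74 ± 0.12. Camera's adjusted p was 0.0002 for the matrix list and 6.5e-05 for the hypoxia list (adjusted p = 0.54 for both with an estimated correlation). Without the tumor block 4 genes were higher and 4 lower. Without E5 in the fit, 3 of 21 matrix genes were higher, and edgeR called 0 of 20 hypoxia genes, of which 4 had an unadjusted p under 0.05.

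**Figure D4:**
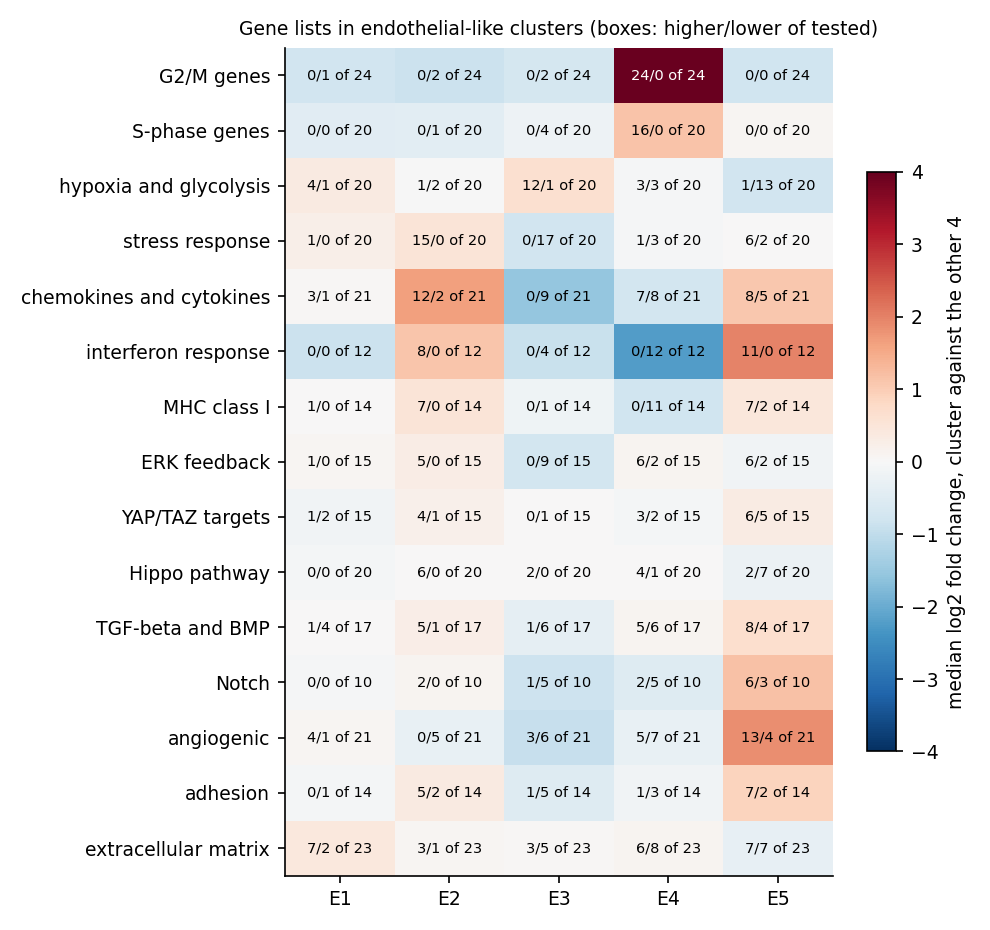
Median log2 fold change (color) of 15 gene lists in each endothelial-like cluster against the mean of the other 4, with the number of genes higher and lower of those tested written in each box. All 24 G2/M genes were higher in E4, and 12 of 20 hypoxia genes were higher in E3.

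Dividing cells were counted by UMIs of Mki67 or Top2a, both expressed in cycling cells. In cells thinned to 1500 UMIs the share was 8.22% ± 1.48 (SD, n = 2) in E4 and between 1.00% and 1.64% in E1, E2, E3 and E5. It was 6.08% ± 0.83 in macrophage-like cells, 4.54% ± 2.81 in T-cell-like cells, and 0.81% ± 0.10 in B-cell-like cells, which served as background. Unthinned, the shares were 21.6%, 14.6%, 9.09% and 2.38% for E4, macrophage-like, T-cell-like and B-cell-like cells, at median depths of 8958 and 13163, 6676 and 8456, 2332.5 and 2630, and 2323 and 2892.5 UMIs.

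Macrophage-like cells held 122 listed genes higher and 94 lower of 370 than the other classes (127 and 99 adjusted over the list alone). Of the macrophage state genes 19 of 21 were higher, such as the scavenger receptor Marco (8.50 ± 0.38). Chemokines and cytokines were higher for 20 of 33, with Il1b at 7.40 ± 0.24 and Ccl6 at 8.58 ± 0.37. All 9 MHC class II genes were higher, with the lysosomal protease Ctss at 6.13 ± 0.26. The receptor kinase Axl was higher by 6.02 ± 0.30 and Spp1 by 4.50 ± 0.41. For these 3 lists camera gave adjusted p of 2e-12, 2.6e-05 and 7e-09, and 0.17, 0.67 and 0.67 as adjusted p with an estimated correlation.

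Fibroblast-like cells held 167 genes higher and 43 lower (169 and 47 adjusted over the list alone). Matrix genes were higher for 26 of 27, including periostin, Postn (8.60 ± 0.27), and the protease Mmp2 (9.56 ± 0.43). The contractile gene Acta2 was higher by 6.56 ± 0.30 and the YAP/TAZ targets Ccdc80 and Tgfb2 by 6.97 ± 0.22 and 4.58 ± 0.43. Of the YAP/TAZ targets 12 of 19 were higher and 1 lower, so this list was not a feature of endothelial-like cells alone. The same held for ERK feedback genes (13 of 16 higher, 0 lower) and angiogenic genes (10 of 19 higher, 1 lower). It also held for the TGF-beta and BMP list (10 of 17 higher, 2 lower) and stress genes (11 of 20 higher, 1 lower). In the Hippo and Notch lists 7 of 21 and 4 of 9 were higher, and 3 and 1 lower. The adjusted p of camera was 6.4e-21 for matrix genes and 0.00014 for YAP/TAZ targets, and 0.13 and 0.38 as adjusted p with an estimated correlation.

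In T-cell-like cells 78 genes were higher and 78 lower (82 and 92 adjusted over the list alone), with 51 lower without the tumor block. Checkpoint and costimulatory genes were higher for 13 of 21, including Pdcd1, which encodes PD-1 (8.43 ± 0.45), Icos (8.56 ± 0.31) and Tnfrsf4 (8.93 ± 0.39). The cytokines Ifng and Tnfsf11 were higher by 8.88 ± 0.41 and 8.76 ± 0.30. B-cell-like cells had 37 genes higher and 202 lower (36 and 209 adjusted over the list alone), with all 9 MHC class II genes higher (H2-Aa 4.93 ± 0.29), together with the costimulatory ligand Cd86 (5.49 ± 0.25). Camera's adjusted p was 4.7e-06 for checkpoint genes in T-cell-like cells and 8.1e-08 for MHC class II genes in B-cell-like cells, and 0.6 and 0.29 as adjusted p with an estimated correlation.

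The tumors were also set side by side within each class. With 1 library per tumor there was no test, and the intervals cover counting error only. In endothelial-like cells 112 of 12139 genes were at least 4-fold higher in tumor 1 and 100 in tumor 2, but 106 and 115 with library-size scaling in place of TMM. E2 held 1401 of the 2723 endothelial-like cells of tumor 1, and E1 held 1393 of the 2474 of tumor 2. Gbp2 stood at 220 CPM in tumor 1 (exact Poisson interval 213 to 226) and 14.0 CPM in tumor 2 (12.6 to 15.5), a 15.6-fold difference. Vcam1 was 6.79-fold higher in tumor 1, at 229 and 33.7 CPM. The interferon-induced chemokine Cxcl9 stood at 17.3 CPM in tumor 1 and 0.529 CPM in tumor 2. The hypoxia-induced carbonic anhydrase Car9 stood at 0.251 CPM in tumor 1 and 8.32 CPM in tumor 2. As a list, 10 of 11 interferon genes and 13 of 14 MHC class I genes were higher in the endothelial-like cells of tumor 1, with median log2 ratios of 1.24 and 1.01. Stress genes, which also answer to handling, were higher there for 18 of 20 (median 0.44). In fibroblast-like cells 14 of 20 were higher in tumor 1 (median 0.22). The counts were 9 of 20 in macrophage-like cells (median −0.01), 7 of 20 in T-cell-like cells (median −0.19) and 2 of 20 in B-cell-like cells (median −0.33). Only 2 of 20 hypoxia genes were higher in the endothelial-like cells of tumor 1, with a median of −0.53.

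In macrophage-like cells hypoxia, MHC class I and interferon genes differed in the same directions, with 6 of 7 interferon genes higher in tumor 1 (median 0.58), but angiogenic genes did not (medians of −0.46 in endothelial-like and 0.33 in macrophage-like cells). Cxcl9 stood at 128 CPM in tumor 1 (114 to 143) and 0.666 CPM in tumor 2 (0.0806 to 2.4). The B-cell attractant Cxcl13 stood at 235 and 7.65 CPM. Arginase, Arg1, stood at 369 CPM in tumor 1 and 2584 CPM in tumor 2, 7.0-fold higher in tumor 2, and the mitophagy gene Bnip3 was 7.17-fold higher in tumor 2. Of the hypoxia list 2 of 19 genes were higher in tumor 1 (median −1.31), against 13 of 14 MHC class I genes (median 0.70). In fibroblast-like cells 6 of 6 interferon genes were higher in tumor 1 (median 0.70), and Spp1 was 7.15-fold higher in tumor 2, at 57.0 and 410 CPM. In T-cell-like cells 39 genes were at least 4-fold higher in tumor 1 and 2 in tumor 2, and the listed ones named by the rule included Ccl2 (358 and 30.4 CPM), Eng and Ptpn14, which were called higher in endothelial-like cells.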

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

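Neutrophil-like cells formed a cluster only under the alternative filter on cells. They were looked at only after the result was seen. When barcodes with 200 or more genes were let in and mitochondrial counts were held to 10%, a cluster with neutrophil markers formed. It held 35 of 3770 cells in tumor 2 (0.928%, 95% Clopper-Pearson interval 0.647% to 1.29%) and 2 of 5417 in tumor 1 (0.037%, 0.004% to 0.133%). The 35 cells lie above the floor of 3 counts set for such signals. Under the filter used for the comparisons, 500 genes and 20%, no neutrophil-like cluster formed. Both limits were changed together, so which of them let the cluster form was not tested.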

How the results depend on the processing

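Settings with E5 left out, the top doublet scores removed, U1 added, and thinned clusters were chosen after seeing the data. Of 230 main values under alternatives other than leaving out a tumor, 171 stayed within 1 SD or, for counts, within 1.5 times. All 34 shares with 1 tumor left out stayed within 1 SD. With 2 tumors each value always lies within 1 SD of their mean, so this was fixed in advance and is no sign of stability. Of 4883 values of named genes under alternatives, 4504 were unchanged in call and, where called, in direction. Of the others, 349 lost the call, 4 gained it, 1 moved and 25 changed direction. The 4504 include 1115 values with 1 tumor left out, for which only the direction could be compared. With 1 tumor left out no test was possible, and 1115 of 1116 log2 fold changes kept their direction, the exception being Cdkn2a, which was not called. The naming rule took only genes changed in the same direction in both tumors. Apart from the genes always included, this result was therefore fixed in advance. For the changes listed here the cause was not tested.

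The block for the tumor mattered most among clusters. Without it the listed genes called higher and lower were 4 and 4 in E1, 24 and 7 in E2, 11 and 38 in E3, and 59 and 32 in E4, and T-cell-like cells had 51 lower. Lists called without the block were 1 lower in fibroblast-like cells, 3 higher in macrophage-like cells, and 1 higher and 3 lower in T-cell-like cells. With an estimated correlation 0 lists were called in the fits of all classes and all clusters. With E5 left out as well, camera called the E2 chemokine list (adjusted p = 0.028), at a negative estimated correlation (−0.026). Without the filter on low counts E1 had 57 higher and 39 lower and E2 31 lower. DESeq2 gave 12 lower in E2. Thinned cells gave 11 lower in E2, 54 lower in E3, and 55 higher and 55 lower in E4; thinning removes counts. With E5 left out 9 were lower in E1, 16 higher in E3 and 57 lower in E4, Fabp5 turned to 0.096 in E1, 0.25 in E2 and 0.434 in E4, and Vgll3 and Epas1 turned to −0.121 and 0.035 in E2.

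In the endothelial-like contrast 52 genes were lower against B-cell-like cells alone, where S100a4 turned to 1.2, Psmb10 to 0.099, Axl to 0.025, Cdkn2a to 2.858 and Top2a to 1.315. Against fibroblast-like cells alone 61 were higher, and Sele turned to −0.275, Kat2a to −0.025, Aurkb to −0.7, Tyms to −0.584, Ccl4 to 0.607, Hspb1 to −0.165, Snai1 to −0.635, Etv4 to −1.969, Epha4 to −0.558, Hey1 to −0.656, Eda2r to −0.429 and Igfbp3 to −0.665. Against macrophage-like cells alone Postn turned to 0.523 and Mki67 to −0.699, and against T-cell-like cells alone Mki67 to −0.721.

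The unnamed share was 0.3% with a filter of 200 genes and 10% mitochondrial counts, 1.72% with tumors clustered alone, where plasma-cell-like cells were 0.14%, and 0.37% with listed genes as features. With the top 5% of doublet scores removed, no plasma-cell-like cluster formed. Plasma-cell-like cells also had the highest median doublet score of the clusters (0.115). Unthinned shares of cells with Mki67 or Top2a were 6.98%, 6.64%, 3.94% and 21.55% in E1 to E4, 7.51% in all endothelial-like cells, and 2.38%, 7.86%, 14.64% and 9.09% in B-cell-like, fibroblast-like, macrophage-like and T-cell-like cells; deeper cells show a UMI more often.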

Other observations

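All tests here except the weighting to a common cluster mix and the count of cells that carry MHC class II UMIs were chosen after the result was seen. T-cell-like cells were led by Il17a, the gene for the cytokine interleukin 17A. Il17a stood at 1675 CPM in tumor 1 and 1006 CPM in tumor 2, with a UMI in 32.4% and 21.5% of T-cell-like cells thinned to 1500 UMIs (31.9% and 20.7% unthinned, medians of 2332.5 and 2630 UMIs). In B-cell-like cells, taken as background, Il17a UMIs were seen in 0.88% and 0% of thinned cells, at medians of 2323 and 2892.5 UMIs. The unnamed cluster U1 held Prox1 at 1197 and 932 CPM, above all named clusters, and Malat1, a nuclear RNA, at 81931 and 46675 CPM, against 5085 to 12136 CPM in E1 to E5. What U1 consists of was not tested.

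Prox1 marked E1 to E4 and not E5. Lower depth in E5 was argued against by the thinned cells, in which the lowest lower bound of E1 to E4 lay 13.9 percentage points above the highest upper bound of E5. Free RNA was argued against by a gap of 21.9 points to B-cell-like cells. Whether E1 to E4 hold the tumor cells and E5 vessel cells of the host stays open, since the counts do not show the fusion and no label marks tumor cells. Camta1 was at −0.58 and Wwtr1 at −0.85 in E5. In a fit of E1 to E4 alone, their largest differences of either sign were rises in E2, at 0.65 and 0.67. Neither gene's fall in E5 exceeded that size by more than its SE. The lowest values in that fit were −0.35 for Camta1 and −0.24 for Wwtr1, both in E3. In E5 both genes lay below these by more than their SE. The outcome depends on whether rises are counted, so these genes do not decide it.

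Interferon genes were higher in the endothelial-like cells of tumor 1, with a median log2 ratio of 1.19 over 11 genes without TMM scaling. Free RNA from immune cells was argued against, since 8 of the 11 genes stood higher in the endothelial-like cells of tumor 1 than in each of its macrophage-like, B-cell-like and T-cell-like cells. Weighted to the cluster mix of tumor 1, the median was 0.11 (95% bootstrap interval over genes −1.21 to 1.19), with 6 of 11 above 0, Gbp2 at 2.09 and Ifit1 at −2.06. The weights were shares of UMIs, of which E2 held 12804600 of 20256900 in tumor 1. Most of the weight in tumor 2 thus fell on its 94 E2 cells. The interval over genes does not cover the error from so few cells. The weighting lowered all 11 ratios, so the cluster mix goes with part of the difference. Listed genes had no part in the clustering, but unlisted genes that vary with them did. E2, which held most of its cells from tumor 1, was itself led by Gbp2. The weighting may thus hold fixed part of the interferon difference it is meant to explain. Whether the cluster mix is the cause, in part or whole, stays open. The weighted values lay on both sides of 0, and the interval holds both 0 and the unweighted 1.19. Interferon genes were higher in tumor 1 in macrophage-like and fibroblast-like cells too (medians of 0.58 and 0.70). Whether free RNA from endothelial-like cells contributed there was not tested.

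MHC class II RNA in E5 of tumor 1 came mostly from few cells. Free RNA as the whole source was argued against, since the best mix of B-cell-like and macrophage-like RNA predicted 75.6 UMIs of 9 other genes of those classes where 50 were seen (Poisson interval 37.1 to 65.9). A few mixed cells would give an uneven spread, and 2 of 118 cells held 163 of the 232 UMIs of H2-Aa, H2-Ab1 and H2-Eb1. The counts of the 9 genes include these 2 cells. Cells mixed with B-cell-like or macrophage-like cells would bring the same genes, so the shortfall does not tell mixed cells from free RNA. It also does not bear on free RNA in the remaining cells. Whether the 2 cells are mixed was not tested. No biological explanation was tested.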
